A study of Mus musculus with 6 samples.

How the data were processed

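Gene expression was measured by RNA sequencing in 6 libraries of mouse glomeruli, 3 PR3_KO and 3 WT, all from animals with diabetic kidney disease. Per the labels' protocols, RNA was extracted with Trizol, selected on oligo(dT) beads and sequenced on a DNBSEQ instrument, so that mainly polyadenylated transcripts were measured. Per the submitters' processing notes, Bowtie2 was used, with the mouse genome build GRCm38.p6. The version, the quantification tool, the annotation, the use of strand and the filters are not given in the sources used here. Per the file headers, the deposited values are FPKM, fragments scaled by transcript length and by the number of mapped fragments, and the authors gave them rounded to 2 decimals with no counts or totals.

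Each file listed 22064 Entrez gene IDs in the same order. The same 3242 IDs were empty in all 6 files, which left 18822 genes, of which 591 were listed at 0 in every library. Symbols and coordinates came from a RefSeq gene table of GRCm38.p6, matched by gene ID. Of the 18822 IDs 18770 matched and 52 did not. The 13 genes of the mitochondrial genome and the genes Xist, Tsix, Ighm, Igkc, Meg3, Lep, Mx1 and Mx2 were not analysed here. FPKM is scaled by the mapped fragments of a library. When abundant transcripts take a larger share of these fragments, the FPKM of all other genes can move down. Their abundance relative to each other need not change. The sum of FPKM is not fixed, so a gene's share of that sum is not its share of fragments.

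The depth of the libraries was read from the lowest values. Among 46 single-exon olfactory receptor genes with a median length of 939 nucleotides, the most common value above 0 was 0.07 FPKM in 5 libraries and 0.08 FPKM in WT 1. Taken as 1 fragment over the whole gene this gives 15200000 and 13300000 fragments, with a range of 12500000 to 16400000 from the rounding. The step was carried by 2 to 6 genes per library, so the depth is a rough estimate. In PR3_KO 2, 2 of these genes lay below that step, for which the cause was not tested, and counts were not derived. A gene of about 939 nucleotides near 0.07 FPKM therefore stands for about 1 fragment, and genes under 1 FPKM were not tested in the main comparison.

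The test fixed before the data were examined depended on the unit: a count-based test for counts, and for FPKM the one used here. It was limma 3.58.1 with statmod 1.5.0 in R 4.3.3, fitted to log2(FPKM + 1) of the 12388 genes with a mean of at least 1 FPKM, with genotype as the only term and an intensity trend and robust variance moderation. P-values were adjusted by the Benjamini-Hochberg method over all tested genes, with a threshold of 0.05. No libraries were left out. Fold changes are PR3_KO minus WT on that log2 scale, and their SE is limma's moderated one. Genes under the filter were compared by an exact two-sided permutation test of their FPKM, which with 3 against 3 libraries cannot go below p = 0.1. Files were read with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.

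The 33 gene lists were fixed before the data were examined. They covered neutrophil granule genes, genes flanking Prtn3, receptors and substrates of neutrophil proteases, markers of kidney and blood cell types, and pathways. The cell types were podocyte, glomerular endothelium, mesangium with smooth muscle and renin cells, parietal epithelium, proximal tubule, loop with distal tubule and collecting duct, macrophage, lymphocyte, erythroid, fibroblast and adipocyte. The pathways were apoptosis, p53 targets, extracellular matrix, inflammation, interferon response, nuclear and mitochondrial oxidative phosphorylation genes, oxidative stress, unfolded protein response, immediate early genes, fatty acid oxidation, sterol synthesis, glycolysis, renin-angiotensin, cell cycle, complement and coagulation, tubular injury, sex-linked genes and ribosomal proteins. Several lists share members, as with Krt8, Krt18, Slc4a1, Fas and Bax. For each list the members past the threshold were counted over all genes and adjusted over the list alone. The 30 lists with at least 5 tested members entered camera with a preset inter-gene correlation of 0.01, adjusted over lists. With a correlation estimated from the residuals, 0 of the 10 lists that passed camera still passed. Fry was run beside it. It tests whether a list's genes move, on balance, one way, and does not compare them with other genes. A list's score in a library is the mean log2(FPKM + 1) of its tested members.

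The genes named follow a rule fixed before the data were examined. It took a set that included Prtn3, Elane, Nphs1, Wt1, Bax and Bcl2, then the 12 rising and 12 falling genes with the largest absolute log2 fold change among those with adjusted p under 0.05, no overlap between genotypes and a mean of at least 1 FPKM, leaving out predicted genes. From each list it took up to 4 members with the smallest adjusted p, or the 2 most abundant where none passed. Members outside the rule are marked where they stand, and some genes the rule took are not reported here. Ctsg, Mpo and S100a8 were also named after their values were seen.

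The alternatives fixed in advance that fit FPKM were a pseudocount of 0.1, no filter, limma without the trend, the replicate number as a block, the proximal tubule score as a covariate, haemoglobin genes left out with sums made equal, each library left out in turn, an adjusted p under 0.1, an absolute log2 fold change of at least 1, camera with an estimated correlation, and fry. Alternatives added after seeing the data were median-of-ratios scaling of the FPKM over genes above 0 in all libraries, a filter of 1 FPKM in at least 3 libraries, and leaving out WT 2 and PR3_KO 3 together. The test was tried on simulated data made from the 12388 genes of this comparison, 3 libraries against 3. Of 100 genes changed 2-fold it recovered 90, of 100 changed 1.5-fold it recovered 39, and 3 of its 132 calls were genes with no simulated change. The simulated noise was independent between genes, few genes changed, and as many rose as fell. The real comparison has correlated genes and many more changes, mostly downward as deposited, so these rates may not hold for it.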

Results

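RNA was sequenced from isolated glomeruli, the filtering units of the kidney, of C57BL/6J mice with diabetic kidney disease. The 6 libraries fell into 2 groups of 3: mice lacking proteinase 3 (PR3_KO) and wild-type mice (WT). Proteinase 3 is a serine protease of neutrophil granules, encoded by Prtn3. The design asks what its absence changes in the diabetic glomerulus and its podocytes, the epithelial cells that cover the glomerular capillaries. Values are FPKM, given as mean ± SD over the 3 libraries of a genotype (n = 3 per genotype), and fold changes are log2 of FPKM + 1, PR3_KO minus WT, which understates the change of low genes. The labels do not say that the libraries came from separate animals, so p-values measure only the spread between these samples, which may be technical.

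The FPKM of the PR3_KO libraries summed to 604697, 576734 and 566772, and those of the WT libraries to 520162, 494316 and 543564. The kidney androgen-regulated protein gene Kap, an abundant proximal tubule transcript, alone made up 9.52%, 8.65% and 7.15% of the sum in PR3_KO and 3.56%, 1.06% and 3.05% in WT. The 10 most abundant genes of a library took 19.7% to 22.2% of the sum in PR3_KO and 9.1% to 12.6% in WT. Between 16473 and 16965 genes were above 0 per library. The steps of the lowest values, read over single-exon olfactory receptor genes, put the depth near 15200000 fragments in 5 libraries and 13300000 in WT 1, if each step, carried by only 2 to 6 genes per library, is 1 fragment over the full gene length. Spearman correlations between libraries were 0.986 to 0.988 within PR3_KO, 0.967 to 0.988 within WT and 0.882 to 0.961 between genotypes. The first principal component held 81.8% of the variance and separated the genotypes, with WT 2 farthest out at 57.9 against 21.3 and 31.7 for the other WT libraries.

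Prtn3, the targeted gene, was measured at 0.14, 0 and 0.07 FPKM in PR3_KO 1, 2 and 3 and at 0.46, 0.21 and 0.22 FPKM in WT 1, 2 and 3 (0.07 ± 0.07 against 0.297 ± 0.142, n = 3 per genotype, exact two-sided permutation p = 0.1, the smallest that 3 against 3 can give). The gene lies on the plus strand of chromosome 10 from 79879667 to 79883174 (GRCm38.p6), with 5 exons and 1025 exonic nucleotides in its annotated transcript, so these levels stand for very few fragments and the check of the labels is a weak one. Elane, the neutrophil elastase gene next to it, was at 0.0233 ± 0.0404 FPKM in PR3_KO and 0.183 ± 0.123 in WT (exact two-sided permutation p = 0.1, n = 3 per genotype). For the cathepsin G gene Ctsg and the myeloperoxidase gene Mpo the exact two-sided permutation p was 1 (n = 3 per genotype). All 4 genes lay below the expression filter of a mean of 1 FPKM and had no limma test.

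Of the 14 tested genes of the neutrophil list, 1 rose and 2 fell (the same numbers adjusted over the list alone), and the list's median log2 fold change was -0.53 (camera adjusted p = 0.974). The neutrophil surface gene Ly6g rose from 0.523 ± 0.205 to 1.76 ± 0.729 FPKM (log2 fold change 0.84, SE 0.20, limma adjusted p = 0.0111). The integrin subunit genes Itgb2 and Itgam, which macrophages also express, fell by 2.02 and 1.20 (limma adjusted p = 0.00244 and 0.0130), the second no longer past the threshold without PR3_KO 1 (-1.04, limma adjusted p = 0.054). S100a8, a subunit of the neutrophil protein calprotectin, was at 9.89, 10.72 and 134.33 FPKM in PR3_KO 1, 2 and 3 against 65.29, 92.38 and 55.25 in WT. The neutrophil score, the mean log2(FPKM + 1) of the list, was 3.41 in PR3_KO 3 against 1.55 and 1.40 in the other PR3_KO libraries and 2.61 to 3.20 in WT. Without PR3_KO 3 the list's median was -1.27 (camera adjusted p = 0.0017), and it was -0.32 without PR3_KO 1 and -0.31 without PR3_KO 2. Camera was run at a preset correlation of 0.01; the one estimated for this list over all 6 libraries was 0.89 (adjusted p = 0.993).

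Among the receptors, inhibitors and substrates of neutrophil serine proteases, 10 of 19 tested genes fell and 0 rose (10 adjusted over the list alone), with a median of -0.75, which is -0.49 relative to the median of all genes (camera adjusted p = 0.273). The thrombin receptor gene F2r fell from 113 ± 24.8 to 44.4 ± 8.63 FPKM (log2 fold change -1.32, SE 0.20, limma adjusted p = 0.00159). The cytokine gene Tnf fell from 3.35 ± 1.82 to 0.193 ± 0.0874 FPKM (log2 fold change -1.79, limma adjusted p = 0.00177). The list passed camera without PR3_KO 3 (median -0.96, adjusted p = 0.032) and with median-of-ratios scaling (-0.47, adjusted p = 0.038), against an estimated correlation of 0.31 (adjusted p = 0.87). Near Prtn3 on chromosome 10, 7 of 21 tested genes fell and 2 rose (7 and 2 adjusted over the list alone, 5 and 6 with median-of-ratios scaling), and the median of -0.15 turned to 0.18 with that scaling. The share that fell was no higher than the 5091 of 12388 over all tested genes. Camera ranked this list toward the higher side of all genes (adjusted p = 0.625), opposite to the sign of its unscaled median. The calponin gene Cnn2 had the smallest adjusted p of the list (log2 fold change -1.44, SE 0.18, limma adjusted p = 0.00106), and the members that rose, Palm and Wdr18, are named after their values were seen (0.45 and 0.37).

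Among the 12 genes with the largest falls in PR3_KO, the complement component genes C1qc, C1qa and C1qb, expressed by tissue macrophages, fell by 3.89, 3.76 and 3.64 on the log2 scale (limma adjusted p = 0.00217, 0.00166 and 0.00262). Without WT 2 and PR3_KO 3 together the calls of C1qc, C1qa and C1qb were lost at log2 fold changes of -3.48, -3.36 and -3.16 (limma adjusted p = 0.1, 0.09 and 0.1), and C1qb lost its call with the replicate number as a block (limma adjusted p = 0.052). C1qc was at 107 ± 48.2 FPKM in WT and 6.71 ± 5.18 in PR3_KO. The macrophage metalloelastase gene Mmp12 fell from 19.1 ± 7.50 to 0.473 ± 0.170 FPKM (limma adjusted p = 0.000598). Chil3, a chitinase-like gene of activated macrophages, fell by 3.69, and the lysosomal protease gene Ctss by 3.40 (limma adjusted p = 0.00127 and 0.000838). The other genes in the group of 12 were Aif1, Clec12a, Fcgr4 and Mpeg1, all expressed in macrophages or other myeloid cells, Bcl2a1b, a member of the Bcl2 family with near-identical paralogs whose value is uncertain, and Pou1f1. Bcl2a1b and Fcgr4 lost their calls without WT 2 and PR3_KO 3 (limma adjusted p = 0.054 and 0.061), and Fcgr4 also with the block (limma adjusted p = 0.055). Pou1f1, known as a transcription factor of the pituitary, was at 15.9 ± 6.39 FPKM in WT and 0.45 ± 0.229 in PR3_KO (log2 fold change -3.48, SE 0.26, limma adjusted p = 0.000598).

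Among the 12 genes with the largest rises, the phosphate transporter gene Slc34a3 went from 2.50 ± 0.541 to 17.2 ± 2.38 FPKM (log2 fold change 2.38, SE 0.15, limma adjusted p = 0.000598). The organic anion transporter gene Slc22a8 went from 82.5 ± 9.67 to 311 ± 78.1 FPKM, and the DNase I gene Dnase1 from 267 ± 99.7 to 1159 ± 279 FPKM (limma adjusted p = 0.000798 and 0.00131). Kap rose from 13450 ± 7170 to 49340 ± 8530 FPKM (log2 fold change 2.06, SE 0.46, limma adjusted p = 0.00812). Cyp24a1, the enzyme that inactivates vitamin D, rose by 2.69, and Hpd, an enzyme of tyrosine breakdown, by 3.04 (limma adjusted p = 0.00838 and 0.00641). Without WT 2, Hpd was no longer past the threshold (2.76, limma adjusted p = 0.057), and without WT 2 and PR3_KO 3 neither Hpd nor Cyp24a1 was (2.91 and 3.02, limma adjusted p = 0.16 and 0.068). Cyp2d12, Cyp2d9, Cyp4a12a and Cyp2a4 belong to cytochrome P450 families with close paralogs, so their log2 fold changes of 3.05, 2.67, 2.17 and 1.94 are uncertain. Zbed5 rose from 30.8 ± 8.55 to 136 ± 16.9 FPKM (limma adjusted p = 0.000684). Rps27rt had the largest rise, 5.21 (SE 0.62, limma adjusted p = 0.00139), at 134.91, 84.40 and 83.06 FPKM in PR3_KO against 0, 4.60 and 2.41 in WT. It is near-identical to the ribosomal protein gene Rps27, whose reads it can share, and its value is uncertain.

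Over all 12388 genes with a mean of at least 1 FPKM, 6545 changed (limma, Benjamini-Hochberg adjusted p under 0.05), of which 1454 rose and 5091 fell. The median log2 fold change of all genes was -0.26 as deposited and 0.03 after median-of-ratios scaling, and with that scaling 3158 rose and 2742 fell. At an absolute log2 fold change of 1 or more, 219 rose and 1160 fell as deposited, and 600 rose and 593 fell with the scaling. PR3_KO and WT libraries did not overlap in 8066 genes (65.1%, against 10% by chance). The number that rose dropped to 917 without PR3_KO 1 and to 943 without PR3_KO 3. With the proximal tubule score as a covariate, which correlated with genotype at 0.87 over the 6 libraries, 22 genes passed (4 higher and 18 lower, limma), and 2320 had an unadjusted p under 0.05.

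**Figure D1:**
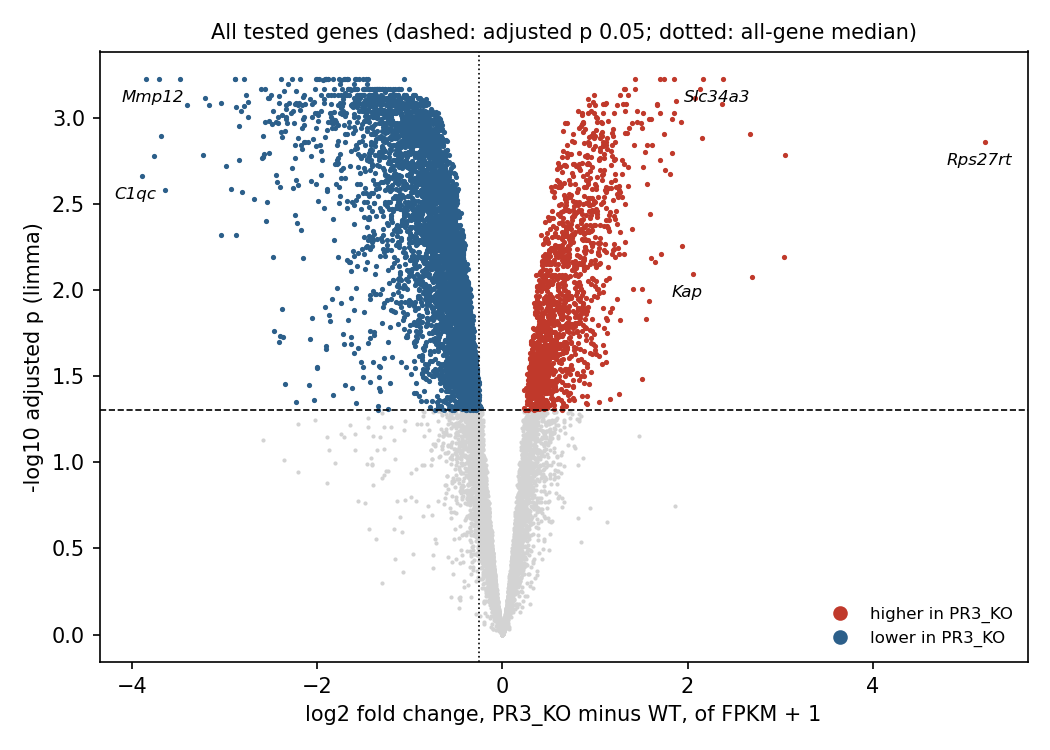
Each point is 1 of the 12388 tested genes, with the log2 fold change of FPKM + 1 (PR3_KO minus WT) on the horizontal axis and -log10 of the limma adjusted p on the vertical axis; red points are the 1454 genes that rose, blue points the 5091 that fell and grey points the rest. The dotted line marks the all-gene median of -0.26, and with median-of-ratios scaling the numbers were 3158 and 2742.

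Proximal tubule genes were higher in PR3_KO. Of 30 tested markers of this segment, which lies next to the glomerulus and reabsorbs most of the filtrate, 21 rose and 0 fell (23 and 1 adjusted over the list alone). The median log2 fold change was 0.80, or 1.06 relative to all genes (camera adjusted p = 3.82e-14, and adjusted p = 0.87 with an estimated correlation). Slc5a2, the glucose transporter of the early proximal tubule, rose from 56.7 ± 17.1 to 192 ± 49.0 FPKM (log2 fold change 1.75, SE 0.27, limma adjusted p = 0.00201). Pck1, an enzyme of gluconeogenesis, rose from 696 ± 241 to 2369 ± 467 FPKM (limma adjusted p = 0.00211), and the cytochrome gene Cyp4b1 rose by 1.34 (limma adjusted p = 0.00123). The score of the list was 8.94, 8.82 and 8.92 in PR3_KO and 8.37, 7.50 and 8.08 in WT. With the score of its own list as a covariate the list's median was -0.06. Pck1 and Cyp4b1 were then at log2 fold changes of 0.62 and 0.88. Slc5a2 was at 1.78, but its SE rose from 0.27 to 0.65 and the call was lost (limma adjusted p = 0.245), as the score correlates with genotype.

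Among the lists of resident glomerular cells, that of the endothelium passed camera, and those of podocyte, mesangium and parietal epithelium did not. All 25 tested markers of the glomerular endothelium fell (25 adjusted over the list alone), with a median of -1.32, or -1.07 relative to all genes (camera adjusted p = 1.13e-07, and adjusted p = 0.87 with an estimated correlation). Sost, which encodes the Wnt inhibitor sclerostin, fell from 68.7 ± 8.84 to 8.69 ± 3.07 FPKM (log2 fold change -2.89, SE 0.22, limma adjusted p = 0.000598). The endothelial transcription factor genes Sox18 and Sox17 fell by 1.90 and 1.33, and Egfl7, a secreted vascular factor, fell from 308 ± 36.1 to 103 ± 11.7 FPKM (limma adjusted p = 0.000598, 0.000684 and 0.000684). With the proximal tubule score as a covariate the median was -0.94, the list still passed camera (adjusted p = 1.8e-09), and 1 member, Sox18, passed (limma adjusted p = 0.0415).

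Of 31 tested podocyte genes, 13 fell and 0 rose (12 and 0 adjusted over the list alone, 6 and 2 with median-of-ratios scaling). Over all 12388 tested genes 5091 fell and 1454 rose, so the number that fell does not set podocyte genes apart. The median was -0.53, which is -0.27 relative to all genes, and the list did not pass camera (adjusted p = 0.151). Nes, the intermediate filament nestin, fell from 60.0 ± 21.8 to 16.4 ± 3.90 FPKM (log2 fold change -1.77, SE 0.26, limma adjusted p = 0.00172). Dach1, a transcription factor, and Cd2ap, a slit diaphragm adaptor, fell by 0.86 and 0.62 (limma adjusted p = 0.00260 and 0.00346). Nphs1, encoding the slit diaphragm protein nephrin, fell from 31.1 ± 8.71 to 19.7 ± 5.29 FPKM (log2 fold change -0.63, SE 0.23, limma adjusted p = 0.0498). It was not past the threshold after median-of-ratios scaling (-0.32, limma adjusted p = 0.217), with no filter (limma adjusted p = 0.076) or without the trend (limma adjusted p = 0.054), nor without PR3_KO 1, PR3_KO 3, WT 2 or WT 3 in turn (limma adjusted p = 0.16, 0.11, 0.11 and 0.06). Wt1, a transcription factor of podocytes, was at 15.2 ± 3.91 and 23.6 ± 7.30 FPKM (limma adjusted p = 0.0697), and passed without PR3_KO 2 (-0.76, limma adjusted p = 0.041), without WT 1 (-0.74, limma adjusted p = 0.041), with the replicate number as a block (limma adjusted p = 0.0029) and with haemoglobin genes left out and library sums made equal (-0.74, limma adjusted p = 0.038). With median-of-ratios scaling Wt1 was at -0.27 (limma adjusted p = 0.298).

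The podocyte list passed camera with median-of-ratios scaling (median -0.23, adjusted p = 0.038, though only 6 members fell and 2 rose), without PR3_KO 2 (-0.65, adjusted p = 0.014) and without WT 1 (-0.64, adjusted p = 0.037), while without WT 2 its median was -0.35. These calls hold at the preset correlation of 0.01, and the one estimated for this list over all 6 libraries was 0.78 (adjusted p = 0.873). Its median turned to 0.19 (camera adjusted p = 0.0018) with the proximal tubule score as a covariate, where 0 members passed (limma). The podocyte score was 3.89, 4.39 and 4.11 in PR3_KO and 4.44, 5.02 and 4.56 in WT.

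Of 18 tested genes of mesangium, smooth muscle and renin cells, 9 fell and 0 rose (9 adjusted over the list alone), with a median of -0.70 (camera adjusted p = 0.166). The smooth muscle actin gene Acta2 fell from 22.7 ± 6.47 to 10.7 ± 1.62 FPKM (log2 fold change -0.996, SE 0.19, limma adjusted p = 0.00441). The mesangial list passed camera without PR3_KO 2 (-0.82, adjusted p = 0.036), without WT 3 (-0.88, adjusted p = 0.039), with median-of-ratios scaling (-0.43, adjusted p = 0.024) and with the replicate number as a block (adjusted p = 0.015), and its median turned to 0.08 with the proximal tubule score as a covariate (adjusted p = 0.089). The estimated correlation of this list was 0.72 (adjusted p = 0.87). Of 10 parietal epithelium genes, 5 fell and 3 rose (5 and 3 adjusted over the list alone), with a median of -0.41 and a camera call toward the higher side that did not pass (adjusted p = 0.854). Krt8, a keratin also listed among tubular injury genes, rose from 34.6 ± 2.33 to 66.6 ± 2.61 FPKM, while Cd44 fell from 8.53 ± 2.36 to 1.60 ± 0.762 FPKM (limma adjusted p = 0.000776 and 0.00106). Pax2 and Pax8, named after their values were seen, also rose (0.58 and 0.55). The scaffold gene Akap12 and the coactivator gene Ncoa7 fell (-1.22 and -0.79, limma adjusted p = 0.00102 and 0.00384), as did Ncam1 and Krt18, named after their values were seen (-0.61 and -0.70).

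In the loop, distal tubule and collecting duct list, 7 of 21 genes fell and 0 rose (3 and 0 adjusted over the list alone, 2 and 1 with median-of-ratios scaling). The share that fell was no higher than the 5091 of 12388 over all tested genes. The median was -0.45 (camera adjusted p = 0.572), and -0.30 without PR3_KO 3. The proton pump subunit gene Atp6v1g3 fell from 15.8 ± 3.96 to 5.30 ± 1.52 FPKM (log2 fold change -1.42, limma adjusted p = 0.00201), and the anion exchanger gene Slc4a1 fell by 0.89 (limma adjusted p = 0.00214). Of 8 fibroblast and interstitial genes, 7 fell and 0 rose (7 adjusted over the list alone), with a median of -0.72 (camera adjusted p = 0.135). Among them Cd34, which endothelium also expresses, fell by 1.62 and Pi16 fell by 1.295 (limma adjusted p = 0.000853 and 0.000825). The fibroblast list passed camera without PR3_KO 2 (-0.87, adjusted p = 0.042), with median-of-ratios scaling (-0.45, adjusted p = 0.025) and with the replicate number as a block (adjusted p = 0.025), against an estimated correlation of 0.86 (adjusted p = 0.87). Of 9 erythroid genes 1 rose and 1 fell (1 and 1 adjusted over the list alone). The median of -0.19 (camera adjusted p = 0.572) turned to 0.08 with median-of-ratios scaling (camera adjusted p = 0.844). The erythroid median was -0.08 without PR3_KO 1 and -0.80 without PR3_KO 2, and turned to 0.07 without PR3_KO 3. The 2 genes past the threshold were Fech, the enzyme that completes haem (log2 fold change 0.47, limma adjusted p = 0.00499), and Slc4a1, shared with the list above. Haemoglobin Hba-a1 was at 509 ± 423 FPKM in PR3_KO and 604 ± 83.7 in WT (limma adjusted p = 0.378), and without PR3_KO 2, which held 997 FPKM, it was past the threshold (-1.18, limma adjusted p = 0.0037). Of the adipocyte list 2 genes were tested and both rose (2 adjusted over the list alone), the triglyceride lipase gene Pnpla2 by 0.66 and the carbonic anhydrase gene Car3 by 1.04 (limma adjusted p = 0.00722 and 0.0445). Car3 lost its call without PR3_KO 1, PR3_KO 2, WT 1 or WT 2 (limma adjusted p = 0.12, 0.13, 0.075 and 0.11).

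**Figure D2:**
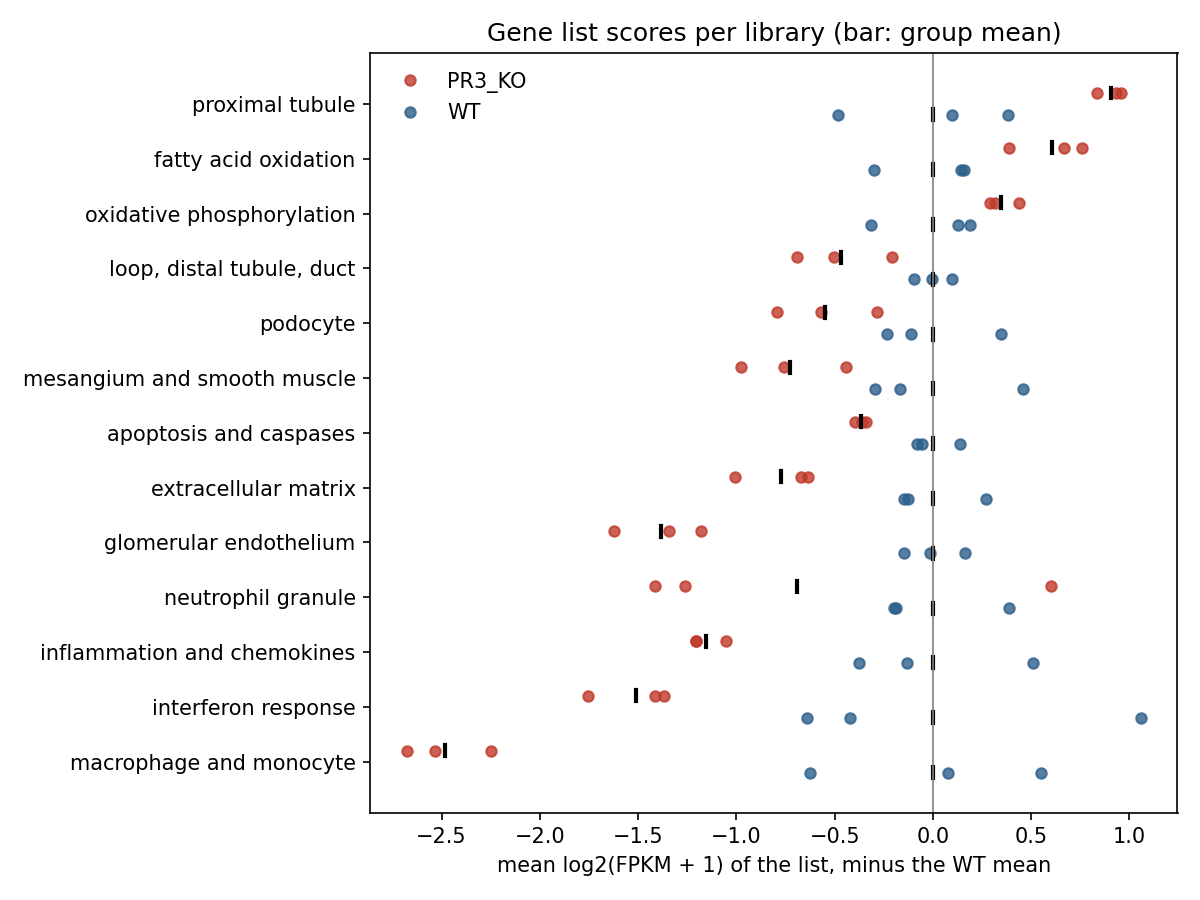
Each point is a library's score for a gene list, the mean log2(FPKM + 1) of its tested genes minus the WT mean, with PR3_KO in red, WT in blue and bars at the group means. The macrophage scores differed by -2.48 and the proximal tubule scores by 0.91 between the group means, and on the neutrophil list PR3_KO 3 lies apart from the other PR3_KO libraries and beside the WT ones.

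Macrophage and monocyte transcripts were far lower in PR3_KO: 24 of 25 tested markers fell and 0 rose (25 adjusted over the list alone). The median log2 fold change was -2.38, or -2.13 relative to all genes (camera adjusted p = 1.13e-07, and adjusted p = 0.87 with an estimated correlation). The fractalkine receptor gene Cx3cr1 fell from 9.09 ± 1.32 to 1.22 ± 0.255 FPKM (log2 fold change -2.18, SE 0.14, limma adjusted p = 0.000598). Laptm5, a lysosomal gene of leukocytes, fell from 67.2 ± 21.2 to 11.99 ± 1.82 FPKM (limma adjusted p = 0.000698). Fcgr1, an Fc receptor gene, and the lysozyme gene Lyz1, a close paralog of Lyz2 whose value is uncertain, fell by 2.32 and 2.89 (limma adjusted p = 0.000633 and 0.000598). The proximal tubule score moved opposite to this list, and with that score as a covariate the median was -1.57, the list still passed camera (adjusted p = 1e-07) and 1 member, Cx3cr1, passed (limma adjusted p = 0.0415). Of 11 lymphocyte genes 4 fell and 1 rose (3 and 1 adjusted over the list alone), with a median of -0.69 (camera adjusted p = 0.625). With the covariate the median turned to 0.37 (camera adjusted p = 8.9e-05 at the preset correlation of 0.01), but 0 members passed (limma). The correlation estimated for the lymphocyte list in the fit without the covariate was 0.55 (camera adjusted p = 0.921). Without WT 2, whose lymphocyte score of 2.80 stood above 1.81 and 2.20 in WT 1 and 3, the median was -0.31. The T cell gene Cd2 fell from 2.12 ± 0.535 to 0.867 ± 0.153 FPKM (limma adjusted p = 0.00666). The B cell gene Cd79b, the T cell kinase gene Lck and, named after its value was seen, the granzyme gene Gzma fell too (log2 fold change -0.62, -0.86 and -1.34), and the immunoglobulin joining chain gene Jchain rose by 0.76 (limma adjusted p = 0.0113, 0.0303, 0.0498 and 0.0359). Lck lost its call without PR3_KO 1, PR3_KO 3 or WT 3 (limma adjusted p = 0.1, 0.072 and 0.055), and Jchain without PR3_KO 2, PR3_KO 3, WT 1 or WT 2 (limma adjusted p = 0.055, 0.082, 0.067 and 0.093).

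Inflammatory genes fell as well. In the NF-kappaB and chemokine list 23 of 30 tested genes fell and 0 rose (24 adjusted over the list alone), with a median of -1.12, or -0.86 relative to all genes (camera adjusted p = 0.00129, and adjusted p = 0.87 with an estimated correlation). The chemokine gene Ccl3 fell from 7.42 ± 2.75 to 0.55 ± 0.296 FPKM, and Sele, the endothelial adhesion molecule E-selectin, from 13.8 ± 4.55 to 1.80 ± 0.950 FPKM (limma adjusted p = 0.000744 and 0.000995). Tlr4, the lipopolysaccharide receptor gene, fell by 1.26 and the inflammatory caspase gene Casp1 by 1.97 (limma adjusted p = 0.000938 and 0.00143). The inflammatory list's median was -0.38 with the proximal tubule covariate, and 0 members passed (camera adjusted p = 0.99).

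Of 33 interferon response genes 25 fell and 0 rose (28 adjusted over the list alone), with a median of -1.50, or -1.24 relative to all genes (camera adjusted p = 0.00138, and adjusted p = 0.87 with an estimated correlation). The antiviral gene Rsad2 fell from 54.6 ± 27.2 to 9.28 ± 1.56 FPKM (log2 fold change -2.34, SE 0.30, limma adjusted p = 0.00120). Isg15, a ubiquitin-like modifier, Oas1a, an RNA sensor, and Usp18, a protease that removes Isg15 from proteins, fell by 1.81, 1.74 and 1.47 (limma adjusted p = 0.00185, 0.00225 and 0.00274). The interferon score was 4.63, 6.33 and 4.85 in WT 1, 2 and 3 and 3.52 to 3.90 in PR3_KO, and without WT 2 the median was -0.99. With the proximal tubule score as a covariate the median turned to 0.16 (camera adjusted p = 8.9e-05), and 0 members passed (limma).

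In the complement and coagulation list 17 of 27 genes fell and 5 rose (17 and 5 adjusted over the list alone), with a median of -0.93 (camera adjusted p = 0.344). The anaphylatoxin receptor gene C5ar1 fell from 5.94 ± 1.12 to 0.82 ± 0.291 FPKM, and F10, encoding coagulation factor X, from 6.75 ± 1.78 to 0.743 ± 0.351 FPKM (limma adjusted p = 0.000684 and 0.000753). Properdin (Cfp) and the C3a receptor (C3ar1) fell by 2.001 and 1.60 (limma adjusted p = 0.000937 and 0.000995). The 5 that rose, C2, Cfb, Fga, Cfi and Plau, are named after their values were seen, with log2 fold changes of 1.58, 0.78, 0.80, 0.63 and 0.52. With median-of-ratios scaling the list passed camera (-0.62, adjusted p = 0.028), against an estimated correlation of 0.23 (adjusted p = 0.87), and without WT 2 its median was -0.62. With the proximal tubule score as a covariate the median was -0.31 (camera adjusted p = 0.9). Several of the genes that fell, such as C5ar1, C3ar1 and Cfp, are expressed by myeloid cells, and the macrophage list fell in 24 of its 25 tested genes with a median of -2.38.

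For apoptosis 23 of 44 tested genes fell and 4 rose (23 and 5 adjusted over the list alone, 15 and 8 with median-of-ratios scaling). The median was -0.42, or -0.16 relative to all genes, and the list did not pass camera (adjusted p = 0.364). The pro-apoptotic gene Bax fell from 83.4 ± 3.97 to 60.3 ± 5.92 FPKM (log2 fold change -0.46, SE 0.11, limma adjusted p = 0.0106), and not past the threshold with median-of-ratios scaling (-0.14, limma adjusted p = 0.385). The anti-apoptotic gene Bcl2 fell from 3.45 ± 0.594 to 1.64 ± 0.435 FPKM (log2 fold change -0.76, SE 0.16, limma adjusted p = 0.00671). Both promoters and inhibitors of cell death were among the genes with the smallest adjusted p. Xiap, a caspase inhibitor, fell from 28.8 ± 3.23 to 12.04 ± 1.58 FPKM, the death receptor gene Fas from 40.8 ± 7.59 to 17.8 ± 1.66, and Cflar, an inhibitor of caspase-8 activation, from 42.4 ± 1.80 to 25.9 ± 1.58 (limma adjusted p = 0.000786, 0.00108 and 0.00118). Bok, a Bax relative, rose from 4.51 ± 0.770 to 10.9 ± 2.36 FPKM (limma adjusted p = 0.00172). The others that rose, Bid, Bnip3 and Endog (0.44, 0.60 and 0.55), are named after their values were seen. Transcript levels do not measure dying cells.

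**Figure D3:**
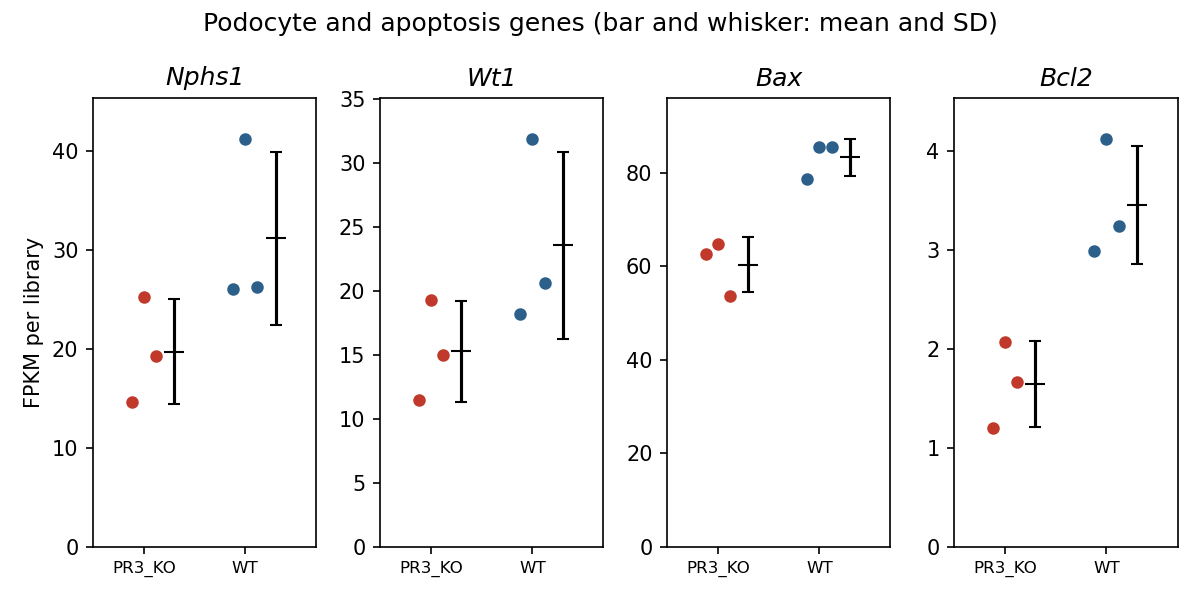
FPKM of the podocyte genes Nphs1 and Wt1 and the apoptosis genes Bax and Bcl2 in each library, with the mean and SD of each genotype beside its 3 points (PR3_KO red, WT blue) on linear axes from 0. Nphs1, Bax and Bcl2 did not overlap between the genotypes, while the Wt1 values did. Of all tested genes 65.1% did not overlap, so this does not set these genes apart.

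Of 22 p53 target genes 13 fell and 2 rose (14 and 2 adjusted over the list alone, 7 and 3 with median-of-ratios scaling), with a median of -0.42 (camera adjusted p = 0.273). Phlda3, an inhibitor of Akt signalling, fell from 36.2 ± 3.44 to 18.1 ± 1.52 FPKM (log2 fold change -0.96, SE 0.11, limma adjusted p = 0.000838). The growth arrest gene Gadd45a fell by 1.15 and the stress response gene Sesn1 by 0.71 (limma adjusted p = 0.00114 and 0.00163). Sesn2 and Perp rose (0.80 and 0.54) and are named after their values were seen. In the tubular injury list 5 of 10 genes fell and 1 rose (6 and 1 adjusted over the list alone), with a median of -0.66 (camera adjusted p = 0.344). The annexin gene Anxa2 fell from 227 ± 26.6 to 91.1 ± 15.1 FPKM, and the adhesion molecule gene Vcam1 from 20.1 ± 8.14 to 4.74 ± 1.49 (limma adjusted p = 0.000935 and 0.00389). Cd24a, a surface glycoprotein gene, and Myc and Krt18, named after their values were seen, also fell (log2 fold change -1.11, -0.62 and -0.70), and Krt8 was the member that rose.

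Extracellular matrix and fibrosis genes fell: 24 of 32 tested genes, with 0 rising (25 adjusted over the list alone, and 13 with median-of-ratios scaling). The median was -0.68, or -0.43 relative to all genes (camera adjusted p = 0.00138, and adjusted p = 0.87 with an estimated correlation). Tgfb1, the fibrogenic cytokine, fell from 77.7 ± 12.7 to 32.4 ± 4.63 FPKM (log2 fold change -1.23, SE 0.15, limma adjusted p = 0.000992), and its receptor gene Tgfbr1 fell by 0.87 (limma adjusted p = 0.000912). The laminin chain gene Lamc1 fell from 18.1 ± 2.52 to 9.12 ± 0.211 FPKM, and the membrane protease gene Mmp14 fell by 1.40 (limma adjusted p = 0.000982 and 0.000992). The matrix list's median with the proximal tubule score as a covariate was -0.23 (camera adjusted p = 0.82).

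Genes of mitochondrial metabolism were higher in PR3_KO. Of 30 fatty acid oxidation genes 18 rose and 0 fell (18 adjusted over the list alone), with a median of 0.61, or 0.87 relative to all genes (camera adjusted p = 3.15e-12, and adjusted p = 0.87 with an estimated correlation). Ppara, the transcription factor that drives these genes, rose from 8.43 ± 2.10 to 28.9 ± 5.21 FPKM (log2 fold change 1.67, SE 0.19, limma adjusted p = 0.000838). Acsl1, an acyl-CoA synthetase, rose by 0.92 (limma adjusted p = 0.000942). The proximal tubule is rich in these transcripts, and with its score as a covariate the list's median was 0.03 with 0 members past the threshold, though it still passed camera (adjusted p = 0.019). Of 59 nuclear genes of oxidative phosphorylation 22 rose and 0 fell (18 adjusted over the list alone), with a median of 0.33, or 0.59 relative to all genes (camera adjusted p = 2.3e-14, and adjusted p = 0.87 with an estimated correlation). The ATP synthase subunit gene Atp5b rose from 1074 ± 153 to 1680 ± 38.1 FPKM, and Cox6a1, a cytochrome oxidase subunit, from 936 ± 169 to 1624 ± 78.8 (limma adjusted p = 0.00961 and 0.00624). Without WT 2 the median of this list was 0.17, and with the covariate it turned to -0.19 (camera adjusted p = 0.98). The 13 genes of the mitochondrial genome were not analysed here.

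Oxidative stress genes moved in both directions: of 34 tested, 10 rose and 7 fell (9 and 7 adjusted over the list alone, 15 and 3 with median-of-ratios scaling). The median was 0.23 and the mean 0.01, and camera called the list higher (adjusted p = 0.00140, and adjusted p = 0.87 with an estimated correlation). Gpx3, the plasma glutathione peroxidase made by proximal tubule cells, rose from 18970 ± 2900 to 41350 ± 1920 FPKM, and the NADPH oxidase gene Nox4 from 49.96 ± 6.42 to 93.2 ± 9.38 (limma adjusted p = 0.00259 and 0.00167). Cybb and Ncf1, subunits of the phagocyte NADPH oxidase, fell by 2.57 and 1.90 (limma adjusted p = 0.00163 and 0.00258). Without WT 2 the median was 0.1, and with the proximal tubule score as a covariate it was -0.16 (camera adjusted p = 1).

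Of 27 immediate early and handling response genes 20 fell and 1, Hspa8, rose (21 and 1 adjusted over the list alone). The median was -0.97, or -0.71 relative to all genes (camera adjusted p = 0.00584, and adjusted p = 0.87 with an estimated correlation). Ier5 fell from 26.6 ± 4.60 to 7.55 ± 0.342 FPKM (log2 fold change -1.68, SE 0.13, limma adjusted p = 0.000598). The transcription factor genes Jun and Klf4 and the GTPase gene Rhob fell (log2 fold change -1.20, -1.496 and -1.45, limma adjusted p = 0.000735, 0.000861 and 0.000825). These genes respond quickly to tissue dissociation, and with the proximal tubule score as a covariate the median was -0.33 (camera adjusted p = 0.44). Hspa8 (0.63, limma adjusted p = 0.0059) is named after its value was seen.

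The remaining lists did not pass camera. Of 20 cell cycle genes 8 fell and 0 rose (8 adjusted over the list alone), with a median of -0.51 (adjusted p = 0.209), and the replication licensing gene Mcm3 fell from 11.4 ± 1.73 to 3.46 ± 0.711 FPKM (limma adjusted p = 0.000794). Without WT 3 this list passed (-0.70, camera adjusted p = 0.0061), against an estimated correlation of 0.42 (adjusted p = 0.87). Of 24 unfolded protein response genes 8 fell and 1 rose (5 and 1 adjusted over the list alone, 2 and 3 with median-of-ratios scaling). Their median of -0.29 (camera adjusted p = 0.749) became 0.03 with that scaling (camera adjusted p = 0.801) and -0.17 without PR3_KO 1. The chaperone gene Hsp90b1 fell by 0.96 and the membrane protein gene Herpud1 rose by 0.88 (limma adjusted p = 0.00302 and 0.00141). In sterol and lipid synthesis 7 of 26 genes fell and 2 rose (7 and 2 adjusted over the list alone, 2 and 4 with median-of-ratios scaling). The median of -0.15 (camera adjusted p = 0.576) turned to 0.16 under the scaling (camera adjusted p = 0.298) and was -0.07 without PR3_KO 1. Of the members that rose Nsdhl went up by 0.53 (limma adjusted p = 0.0194). Nsdhl lost its call without PR3_KO 3 (0.41, limma adjusted p = 0.067).

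In glycolysis and glucose handling 6 of 26 genes fell and 4 rose (6 and 0 adjusted over the list alone, 4 and 11 with median-of-ratios scaling). The median of -0.04 (camera adjusted p = 0.196) turned to 0.26 under the scaling (camera adjusted p = 0.198). It was -0.02 without PR3_KO 1 and -0.08 without PR3_KO 3. The pyruvate kinase gene Pkm fell from 210 ± 22.2 to 104 ± 9.39 FPKM (log2 fold change -1.003, limma adjusted p = 0.00107), while Gpi1, Gapdh, Sord and Pgam1, named after their values were seen, rose by 0.34 to 0.61. Of 12 renin-angiotensin genes 3 rose and 1 fell (3 and 1 adjusted over the list alone). The median of -0.03 (camera adjusted p = 0.175) turned to 0.27 under the scaling (camera adjusted p = 0.119). It was -0.06 without WT 1 and -0.05 without WT 2. The brush border peptidase gene Anpep rose from 36.5 ± 14.3 to 78.3 ± 9.23 FPKM (limma adjusted p = 0.00848). The lysosomal carboxypeptidase gene Ctsa also rose and the prorenin receptor gene Atp6ap2 fell (log2 fold change 0.49 and -0.36, limma adjusted p = 0.00631 and 0.0145), the second losing its call with the scaling (limma adjusted p = 0.732) and without PR3_KO 1 (limma adjusted p = 0.058). Of 45 ribosomal protein genes 10 fell and 0 rose (2 adjusted over the list alone), with a median of -0.17 (camera adjusted p = 0.918). Under the scaling 0 fell and 2 rose, and the median turned to 0.16 (camera adjusted p = 0.119). Without WT 3 the unscaled median was -0.11. Rpl37 was at 102 ± 8.23 FPKM in PR3_KO and 164 ± 9.69 in WT (limma adjusted p = 0.00254, and 0.0649 with the scaling). Y-linked genes were present in all 6 libraries. Of 4 tested, 3 fell and 0 rose (3 adjusted over the list alone), with Ddx3y at 7.52 ± 0.685 FPKM in PR3_KO and 17.4 ± 2.04 in WT (log2 fold change -1.11, limma adjusted p = 0.000773), and their median of -0.56 had no set test. Eif2s3y and Uty fell as well (log2 fold change -0.68 and -0.44, limma adjusted p = 0.00102 and 0.00902), Uty not past the threshold with the scaling (limma adjusted p = 0.173).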

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

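Median-of-ratios scaling, the filter of 1 FPKM in 3 libraries and the fit without WT 2 and PR3_KO 3 were chosen after seeing the data. The planned count-based tests, with their own scaling, filters and CPM, were not run, because the files hold FPKM. The 6545 changed genes stayed within 1.5 times under all settings but the covariate and the fold threshold, from 4754 to 7756 (the latter at an adjusted p under 0.1), and numbered 4986 without WT 2 and PR3_KO 3. With each library left out in turn, 4754 to 6278 changed, 917 to 1514 rose and 3837 to 4764 fell. Scaling by the median of ratios gave 3158 higher and 2742 lower genes, with 4196 of its 5900 calls shared with the unscaled fit in the same direction. It sets the median gene near 0 by construction. Haemoglobin genes left out and sums made equal gave 892 higher genes. An absolute log2 fold change of at least 1 left 1379 genes, 219 higher and 1160 lower. With the proximal tubule score as a covariate 22 passed, 4 higher and 18 lower. The score correlated with genotype at 0.87 and leaves little of the contrast, so a call lost there does not show the absence of a change.

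Of 30 lists 10 passed camera, 15 with median-of-ratios scaling, 6 with the covariate (3 shared in the same direction), 17 by fry (7 shared) and 0 with an estimated correlation, where all 10 medians stood as before: endothelium -1.32, proximal tubule 0.80, macrophage -2.38, extracellular matrix -0.68, inflammation -1.12, interferon -1.50, oxidative phosphorylation 0.33, oxidative stress 0.23, immediate early genes -0.97 and fatty acid oxidation 0.61, each at adjusted p = 0.87. By fry, interferon (-1.50, adjusted p = 0.059), oxidative phosphorylation (0.33, 0.14) and oxidative stress (0.23, 0.44) did not pass and apoptosis did (-0.42, 0.018). Fry read the lists of genes flanking Prtn3 (-0.15), parietal epithelium (-0.41) and glycolysis (-0.04) as lower where camera ranked them higher. Camera ranks test statistics against those of all genes, and the cause of the parietal call was not tested.

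With the covariate, medians turned for podocyte (0.19), mesangium (0.08), lymphocyte (0.37), interferon (0.16), renin-angiotensin (0.16), proximal tubule (-0.06), oxidative phosphorylation (-0.19) and oxidative stress (-0.16), and the genes Nphs1 (0.18) and Lck (0.35) turned without passing. The podocyte, lymphocyte and interferon lists passed camera there as higher (adjusted p = 0.0018, 8.9e-05 and 8.9e-05). Proximal tubule, oxidative phosphorylation, oxidative stress, extracellular matrix (-0.23), inflammation (-0.38) and immediate early genes (-0.33) no longer passed. The podocyte list passed with median-of-ratios scaling (-0.23, with 6 members lower and 2 higher), and its medians with each library left out in turn ran from -0.65 to -0.35. Apart from the change that the scaling makes by construction, the causes of these changes were not tested, those with the covariate included.

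The replicate numbers showed no clear pairing of the libraries. Same-numbered libraries correlated in their deviations from the group means at 0.07, 0.27 and -0.09. PR3_KO 1 and 3 correlated best with other numbers and PR3_KO 2 with its own. With so few libraries per genotype these values cannot exclude a pairing. With the number as a block 6693 genes changed, 1550 higher and 5143 lower, and the podocyte list passed (-0.53, camera adjusted p = 0.0038).

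Of the 151 named genes with a test, 151 kept their direction and side of the threshold with a pseudocount of 0.1, 148 with no filter, 150 without the trend, 146 with the replicate block, 144 without haemoglobin genes and with sums made equal, 135 with median-of-ratios scaling, 143 to 148 with 1 library left out, 135 without WT 2 and PR3_KO 3, and 10 with the covariate. Depth limits genes near 0.07 FPKM, about 1 fragment, such as Prtn3.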

Other observations

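The tests of cell composition, of PR3_KO 3, of proximal tubule segments and of DNA flanking Prtn3, and the count of other splits of the libraries, were chosen after the results were seen, and the test of Rps27 was written before its value was seen.

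The early minus late proximal tubule segment score was higher by 0.9 in PR3_KO (pooled SD 0.41, exact two-sided permutation p = 0.1, n = 3 per genotype, the smallest possible), with 1.84, 2.01 and 2.0 in PR3_KO and 0.86, 1.69 and 0.59 in WT. The 10 genes of each segment were listed after the main results were seen, and members such as Slc5a2, Slc34a3, Slc22a8 and Slc7a13 had known values, so this does not decide whether early genes rose more than late ones.

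Some genes were near on in 1 genotype and near off in the other, named here after their values were seen. Rhox8, a homeobox gene of the reproductive tract, was at 8.73, 4.04 and 12.79 FPKM in WT and 0.23 to 0.26 in PR3_KO. Sncb was listed at 0 in all PR3_KO libraries and at 0.87, 1.34 and 1.45 FPKM in WT, whereas Lypd8 was listed at 0 in all WT libraries and at 2.18, 1.61 and 1.31 FPKM in PR3_KO. Mmp13, a collagenase, was at 7.73 ± 1.95 FPKM in WT and 0.25 ± 0.184 in PR3_KO (n = 3 per genotype).

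The main pattern was a rise of proximal tubule transcripts together with lower macrophage and glomerular endothelial transcripts, the cell type lists that passed camera, though none of the 3 passed with an estimated correlation (adjusted p = 0.87 each). A larger share of proximal tubule alone would lower the others alike, if tubule cells express little of them. Macrophage transcripts fell beyond podocyte ones (difference of scores -1.94, pooled SD 0.41), and so did endothelial ones (-0.83, pooled SD 0.12). The genotypes did not overlap in either difference (exact two-sided permutation p = 0.1 each, the smallest possible). The list medians were known when these differences were chosen, so they are no independent test. Their size still argues against a larger share of proximal tubule as the whole cause of those falls. The fall of podocyte transcripts matched that of the loop, distal tubule and collecting duct (difference -0.08, pooled SD 0.21), so for podocytes a larger share of proximal tubule stays open and could account for their lower level, that of Nphs1 included. The list used for comparison is itself tubule and did not rise (median -0.45), so the match does not speak for more tubule of every segment. Fewer macrophages and endothelial transcripts as an effect of genotype, in diabetic glomeruli, is a hypothesis that these libraries leave open, as is a difference in isolation that the labels do not record. Of 27 immediate early and handling response genes, 20 were lower and 1 higher in PR3_KO (median -0.97), and the design cannot assign this to either. Of the 10 splits of the libraries into 3 and 3, the real one gave 6545 genes and the highest other gave 0 (limma, 16 to 188 genes at unadjusted p under 0.05), and 10 splits are too few for a share under 0.05. Every other split mixed the genotypes in both of its groups. The difference between genotypes then counted as spread within groups, so these counts of 0 do not measure chance.

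The neutrophil genes of PR3_KO 3 stood apart, 1.94 above the mean of the other PR3_KO libraries in list score. Blood carried into that library would bring erythroid transcripts, but its erythroid score of 4.88 was not above 5.04 and 6.13 in PR3_KO 1 and 2. The difference of -0.7 from their mean came mostly from PR3_KO 2, and the score was close to that of PR3_KO 1. A WT library under a wrong label is argued against by its macrophage score, which lay below the lowest WT library (-1.91, against a range of 1.18 within WT). Neutrophils in the tissue of that animal, or a neutrophil-rich part of the blood, remain possible sources that were not tested.

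Genes with a gap of at least 4-fold between the genotypes' nearest libraries numbered 78, of which 9 were higher in PR3_KO and 69 in WT. If flanking DNA from the strain that carried the targeted allele were the cause of the group, these genes would cluster near Prtn3. Of them 1, the predicted gene Gm3055, lay within 10 Mb (1.6% of all tested genes do). This argues against flanking DNA as the cause of the group, with Gm3055 itself left open. It does not show whether flanking DNA was carried along, since the group was picked by its gap and not by position. The group holds many genes of macrophages (6 of them in the macrophage list), whose fall it repeats, and of the 9 genes higher in PR3_KO 0 lay within 10 Mb. For Rps27rt, shared reads could be the source: Rps27 was lower in PR3_KO by more than Rps27rt gained (-357.2 FPKM, and -258.7 for their sum, SD 156.1), so the exchange did not balance and the test cannot decide. Strain differences elsewhere in the genome were not tested.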
